A study of Mus musculus with 2 samples.

How the data were processed

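Gene expression was measured in single cells of mouse cochleae with droplet-based 3' RNA sequencing. Per the labels, the cells came from C57BL/6J mice that carry a GFP reporter at Cx3cr1 and a Thy1-YFP reporter, males and females were pooled, and the cells had been enriched for the surface protein CD11b, which neutrophils, monocytes and macrophages carry. Per the series design text, magnetic beads were used for that selection and the tissue was taken 33 days after a cochlear implant electrode was placed. There was 1 library of implanted cochleae and 1 library of non-implanted cochleae. The series text speaks of opposite ears being collected, but the labels of the 2 samples do not say that the non-implanted cochleae were these, whether the electrode released a drug, or how many animals were pooled. The labels also carry a dissection protocol for other ages and another tissue, which differs from the series design text, so dissociation details are not used here.

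The deposited matrices hold whole-number UMI (unique molecular identifier) counts per gene and cell barcode, without normalization. They were written by Cell Ranger 3.0.1, per the file headers, and the submitters' processing notes name Cell Ranger and Seurat with the mouse build mm10, also called GRCm38. The aligner and the annotation release are not given in the sources used here. Of the 48816 feature rows, 48709 were genes, 92 were ERCC spike-in sequences and 15 were transgenes. The spike-in rows held 11 UMIs in each library (5.61e-05% and 5.10e-05% of the implanted and non-implanted totals). The transgene rows, including those named for EGFP and Venus, held 0 UMIs in both libraries, although the labels name GFP and YFP reporters and Cx3cr1 was detected. Whether the reporters' sequences matched these rows is not known, so the rows are not used as a measure of reporter expression. Those rows were left out of all totals. Of the gene identifiers, 41341 matched GENCODE M21 with their version and 48349 without it, and coordinates are those of GENCODE M21 on GRCm38.

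The implanted library held 3231 deposited barcodes and 19593003 UMIs, and the non-implanted library 3572 barcodes and 21577033 UMIs. The lowest total of any barcode was 501 and 500 UMIs, respectively. Cells with fewer than 200 detected genes or more than 10% mitochondrial UMIs were left out (82 implanted and 59 non-implanted). Doublet scores were computed with Scrublet as implemented in scanpy 1.11.5, and the cells with the highest scores were removed, their number set to 0.8% per 1000 deposited barcodes (84 and 102). This left 3065 implanted and 3411 non-implanted cells with a median of 4239 and 4145 UMIs and 1338 and 1307 genes. The deposited counts were normalized per cell, log-transformed, reduced to 2000 variable genes and 30 principal components, and joined in a graph of 15 neighbours weighted by shared neighbours. Leiden clustering (leidenalg 0.10.2) at a resolution of 1 gave 27 clusters over both libraries together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, R 4.3.3 and edgeR 4.0.16 were used.

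Clusters were named by marker lists of 26 cell types, and a name ends in "-like" because it rests on transcripts alone. A cluster needed at least 3 detected markers of its type. The marker lists, 23 gene lists, the rule for naming genes, the cell filters and most alternatives were fixed before the data were examined. The score that turned markers into names was settled after the clusters had been seen: it compared each marker with its 20th percentile over the clusters, averaged the 8 highest markers and let the next type take the name where the scores lay within 10% of each other and the leading genes favoured it. The clusters named macrophage-like, monocyte-like, neutrophil-like and granulocyte precursor-like had at least 100 cells in each library and were compared gene by gene.

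With 1 library per group there was no replicate check. No test was made, no p-value is given, and cells were not treated as replicates. Shares of cells carry exact Clopper-Pearson 95% intervals, differences of shares Newcombe intervals, CPM values (UMIs per 1e6) exact Poisson intervals, and ratios of CPM exact conditional intervals. All of these cover counting error only and not the spread between animals or between libraries. Those of CPM and ratios take UMIs as independent draws. They leave out the spread between cells and are too narrow where few cells hold the counts. Counts were summed per library over the cells of a class and divided by the class's total to give CPM, and the log2 ratio was that of CPM plus 5, implanted over non-implanted. For a value of 0 the upper bound of its exact interval is given. For a gene list, the median log2 ratio over members with at least 20 UMIs in both libraries together was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. A percentile under 2.5 or above the mirrored upper bound is called outside the central range. Some genes are members of more than 1 list, so the lists are not independent.

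Named genes of macrophage-like cells were the 12 with the highest and the 12 with the lowest log2 ratio among genes with at least 100 UMIs in both libraries together and at least 50 CPM in 1 library. Mitochondrial, ribosomal protein, hemoglobin, immunoglobulin, sex-linked, clone-named and predicted genes and markers of other classes were left out. A clone-named transcript whose name has a form the rule did not foresee came through among the 12 lowest and was kept in the medians. In the other 3 classes the 5 highest and 5 lowest were taken, and of each list described up to 2 members on each side with at least 50 UMIs. Counts of genes past a fixed size had been planned as a summary as well. They were computed and moved by over 1.5 times in 13 of 38 comparisons with alternatives in macrophage-like, 12 of 18 in precursor-like, 9 of 18 in monocyte-like and 5 of 18 in neutrophil-like cells, and they are not reported, because with 1 library per group such a count has no error. Medians over the named genes replaced them, a choice made after the counts had been seen, and the interval of such a median comes from 2000 Poisson draws.

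The gene comparison was tested on simulated data, with counts drawn for 9849 genes from the means and totals of the macrophage-like cells and 200 genes changed. Of 50 genes at each size, 50 changed 4-fold, 49 changed 2-fold, 45 changed 0.5-fold and 50 changed 0.25-fold passed a 1.5-fold difference in the right direction. Of 9649 unchanged genes, 16 passed a 2-fold difference in either direction, and those past 1.5-fold were not counted. The intervals held the simulated ratio in 94% to 98% of the changed genes. Of 200 simulated unchanged lists, 6% lay outside the central range, and a doubled list lay at percentile 100. These draws hold counting noise only, and the unchanged lists were random genes, so members that vary together are not covered.

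The alternatives covered no cell filter and a stricter one, no doublets or 2 times the doublets removed, Leiden resolutions of 0.5 and 2, more variable genes and components, separate clustering of the libraries, edgeR TMM and median-of-ratios scaling, thinning to 1000 UMIs per cell, equal weight for every cell, pseudocounts of 1 and 20 CPM, and UMI minimums of 100 and 1. For shares, the denominator was limited to white blood cell classes. Alternatives chosen after the data were seen left out 1 of the macrophage-like clusters, each gene's top cell, or the genes that differed from the clustering, or gave each cluster of the other classes the same weight in both libraries.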

Results

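CD11b-selected cells of implanted and non-implanted mouse cochleae were compared 33 days after implantation, with 1 library of each kind. After filtering, 3065 cells with 18469428 UMIs remained in the implanted library and 3411 cells with 20433645 UMIs in the non-implanted library. Ptprc, which encodes the leukocyte antigen CD45, was detected in 90.0% and 93.1% of the cells. Cx3cr1, the locus of the GFP reporter, had 70.4 and 67.8 UMIs per 1e6 (CPM) over all cells. Itgam, the gene for CD11b itself, had 0 UMIs in both libraries, so the transcript gave no check of the selection. Xist was present at 84.6 and 104 CPM and the Y-linked Ddx3y at 55.7 and 54.1 CPM, and both libraries thus held cells of both sexes. There were no replicates, and the intervals given here cover counting error only, except where a range over list members is named.

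The first comparison asked which cell types the implanted and non-implanted libraries held after CD11b selection. Cells of the neutrophil lineage made up most of both libraries, and their share was lower in the implanted one, at 75.9% (95% interval 74.3 to 77.4) against 81.9% (80.5 to 83.2). Monocyte-like cells were a larger share of the implanted library, with 316 of 3065 cells or 10.3% (9.26 to 11.4), than of the non-implanted library, with 265 of 3411 cells or 7.77% (6.89 to 8.72). Macrophage-like cells made up 8.35% (7.40 to 9.39) of implanted and 6.54% (5.73 to 7.42) of non-implanted cells. Erythroid-like cells made up 2.51% (1.99 to 3.13) and 1.20% (0.864 to 1.63).

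Within the neutrophil lineage, neutrophil-like cells were 44.3% of the implanted and 49.9% of the non-implanted library, and granulocyte precursor-like cells 31.5% and 32.0%. Osteoclast-like cells were few, with 11 cells (0.359%) against 27 (0.792%). B cell-like cells numbered 40 and 32, megakaryocyte or platelet-like cells 24 and 21, and fibroblast or fibrocyte-like cells 15 and 9. The differences in share were -5.99 percentage points (-7.99 to -4.00) for the neutrophil lineage, 2.54 (1.14 to 3.95) for monocyte-like and 1.81 (0.536 to 3.11) for macrophage-like cells. These are shares of cells that the CD11b beads retained and not of the cochlea. Which part of the dissected tissue each class came from, precursor-like, erythroid-like and osteoclast-like cells included, cannot be told from these data. The macrophage-like difference was 0.0212 points when each library was clustered on its own (7.14% against 7.12%), and the split between neutrophil-like and precursor-like cells moved with the clustering.

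**Figure D1:**
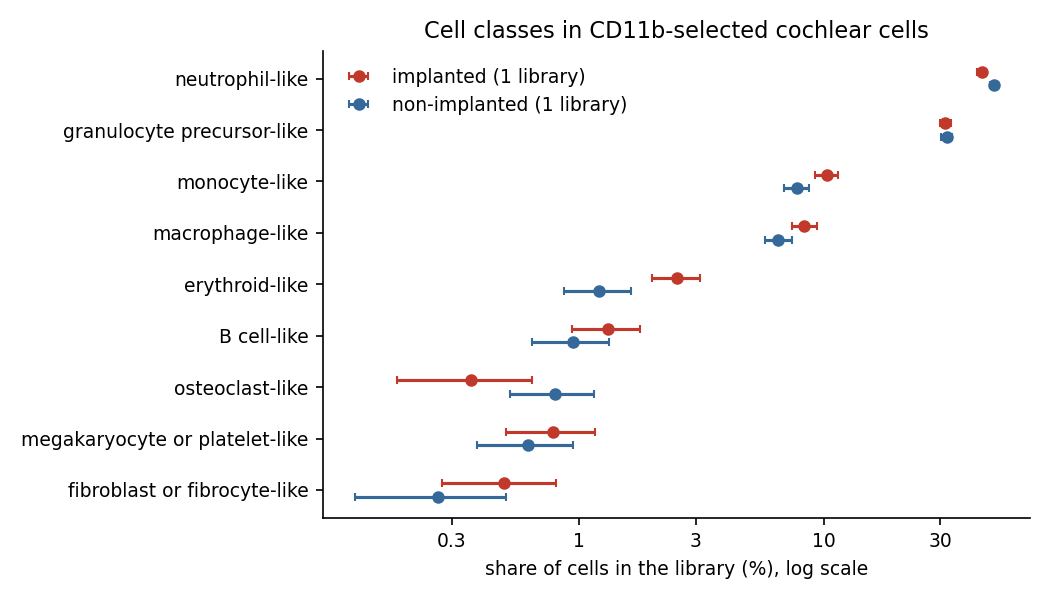
Share of cells per named class in the implanted (red) and non-implanted (blue) library, on a log axis in percent, with exact Clopper-Pearson 95% intervals as bars. Monocyte-like cells lie at 10.3% in the implanted and 7.77% in the non-implanted library, and erythroid-like cells at 2.51% and 1.20%.

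The second comparison asked how macrophage-like cells differed between the 2 libraries. Implanted macrophage-like cells held far more transcript of Spp1, which encodes the matrix protein osteopontin, at 5684 CPM against 65.1 (ratio 87.3, 95% interval 71.1 to 108), and of the macrophage elastase Mmp12, at 1539 against 4.25 CPM (ratio 362, 166 to 988). Gpnmb, a transmembrane glycoprotein gene induced in lysosome-rich macrophages, stood at 1389 against 44.6 CPM (ratio 31.2, 24.3 to 40.7). Mfge8, whose product bridges phagocytes to dying cells, stood at 1402 against 8.49 CPM (ratio 165, 94.3 to 320). Cell-cycle genes and genes of MHC class II presentation were lower in the implanted library. On GRCm38 (GENCODE M21) these genes lie at chromosome 5, 104435118 to 104441050, plus strand (Spp1), chromosome 9, 7344381 to 7369499, plus strand (Mmp12), chromosome 6, 49036546 to 49070929, plus strand (Gpnmb), and chromosome 7, 79133768 to 79149060, minus strand (Mfge8).

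Among the other genes with the highest ratios, the fatty acid-binding protein gene Fabp5 had 749 against 60.2 CPM (ratio 12.5, 10.00 to 15.7), the arginase gene Arg1 had 204 against 7.78 CPM (ratio 26.2, 14.5 to 52.9), and the matrix metalloproteinase gene Mmp19 had 109 against 4.25 CPM (ratio 25.7, 11.6 to 71.0). Mamdc2, Rnf128, Pcdh7 and Ahnak2 had 1 to 3 UMIs in the non-implanted library, with ratios of CPM of 75.6 (20.6 to 629), 39.7 (13.3 to 195), 36.3 (12.2 to 178) and 85.6 (15.0 to 3413). Of the implanted UMIs, 1 cell held 43.9% for Mamdc2 and 30.6% for Arg1. Saa3, an acute-phase protein gene, had a ratio of 89.6 (15.8 to 3571), and 1 implanted cell held 91.1% of its UMIs. The median log2 ratio of these 12 genes was 3.84 (3.68 to 4.20), but 0.69 without cluster 22 of the macrophage-like cells, and 5.05 and 2.79 with pseudocounts of 1 and 20 CPM.

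The genes with the lowest ratios included 6 genes of the cell cycle. Top2a had 27.8 against 99.8 CPM (log2 ratio -1.68), Cenpf 10.2 against 58.0 (-2.05), Ube2c 21.5 against 76.4 (-1.62), Birc5 18.7 against 61.6 (-1.49), the histone gene Hist1h1b 16.4 against 65.8 (-1.72) and Stmn1 84.4 against 220 (-1.33). Ciita, the transactivator of MHC class II genes, had 45.9 against 126 CPM (-1.36). The adhesion gene Negr1 had 90.6 against 264 CPM (-1.49). Cxcl9, an interferon-gamma-induced chemokine gene, had 3.96 against 79.3 CPM, with 55.4% of the non-implanted UMIs in 1 cell. Retnla had 0 UMIs (up to 2.09 CPM by the exact interval) against 165, and all of these lay in 1 non-implanted cell. The median log2 ratio of the 12 lowest genes was -1.55 (-1.77 to -1.43).

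**Figure D2:**
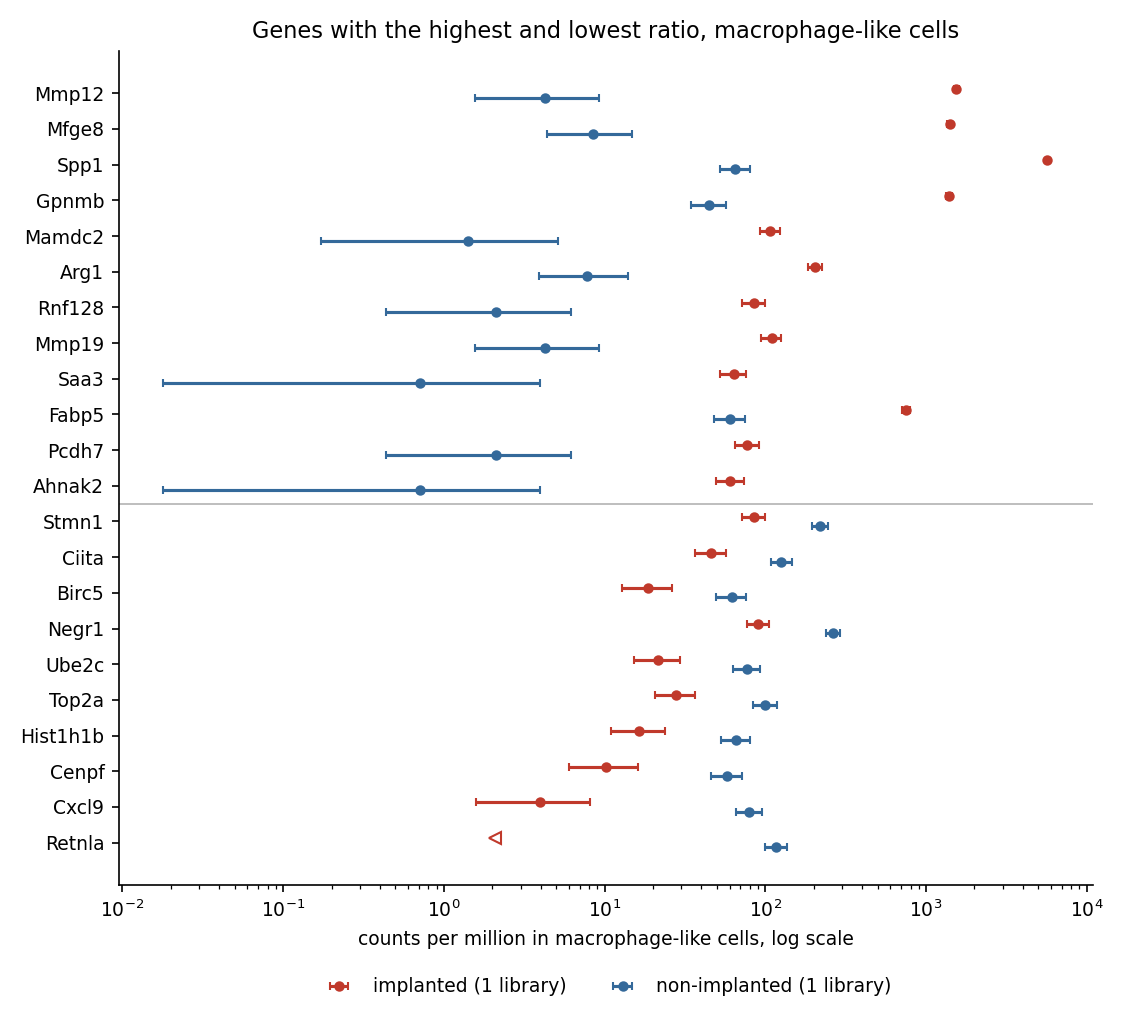
CPM of the genes described in the text that were among the 12 with the highest ratio (upper part) or the 12 with the lowest (lower part) in macrophage-like cells, on a log axis, with exact Poisson 95% intervals as bars and an open triangle at the upper bound where no UMI was counted. Implanted values (red) lie above the non-implanted ones (blue) in the upper part, with Spp1 at 5684 and 65.1 CPM.

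Macrophage-like cells were spread differently over their clusters in the 2 libraries. Cluster 10, the largest in both, led by MHC class II genes and C1qa, held 44.1% of the implanted and 70.9% of the non-implanted macrophage-like cells, and cluster 15, of shallow cells with complement C1q and Apoe, held 27.0% and 24.2%. Cluster 22, led by Mmp12, Mfge8, Spp1 and Gpnmb, held 61 implanted cells (23.8%, 18.7 to 29.5) and 2 non-implanted cells (0.897%, 0.109 to 3.20), and cluster 27 held 13 and 9 cells. When the genes that differed at least 2-fold in macrophage-like cells were left out of the clustering, 60 of the 63 cells of cluster 22 still fell together, in a cluster of 64 implanted and 4 non-implanted cells. A cluster that comes almost wholly from 1 library can reflect that library rather than a cell type.

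Without cluster 22 the ratio of CPM was 4.49 (3.48 to 5.84) for Spp1, 2.70 (2.07 to 3.54) for Fabp5, 1.63 (1.16 to 2.31) for Gpnmb and 5.54 (1.81 to 22.6) for Mmp19. For Mmp12 (12 against 6 UMIs, ratio 2.61, 0.906 to 8.47), Mfge8 (13 against 12, 1.41, 0.594 to 3.39), Arg1 (4 against 6) and Mamdc2 (1 against 2) the difference then lay within counting error. Several of these genes led cluster 22, so leaving it out lowers their ratios by construction. Within cluster 10, Spp1 had 102 CPM in the implanted and 54.6 in the non-implanted library, Lgals3 1224 and 611, and Fabp5 130 and 53.8. The MHC class II gene H2-Aa had 6693 and 7211 CPM in cluster 10, and 372 CPM in the implanted cells of cluster 22.

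The share of macrophage-like cells with a Spp1 UMI was 37.9% in the implanted and 15.7% in the non-implanted library, at median depths of 5392 and 5687 UMIs. Thinned to 1000 UMIs, with 54 and 35 shallower cells left out, it was 28.7% (22.6 to 35.5) and 5.32% (2.58 to 9.56). Neutrophil-like cells, taken as the background, had a Spp1 UMI in 10.1% and 5.64% of cells at median depths of 2820 and 2818 UMIs, and in 4.05% and 2.73% after thinning. Mmp12 was detected in 10.5% and 0.897% of macrophage-like cells (7.92% and 0.532% thinned), against 1.18% and 0% of neutrophil-like cells (0.675% and 0% thinned), where 0 of 1703 cells allows up to 0.216% by the exact interval. H2-Aa was detected in 64.5% and 81.6% of macrophage-like cells (50.0% and 75.5% thinned), against 5.00% and 7.28% of neutrophil-like cells (2.40% and 2.97% thinned).

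Of the 23 gene lists, 14 lay outside the central range of matched random lists in macrophage-like cells, 8 above and 6 below it. In precursor-like, neutrophil-like and monocyte-like cells 11, 10 and 7 lists lay outside it. Leaving the range was thus common in every class, also where medians were small. The list of foreign body response and matrix remodelling genes had the highest median log2 ratio, 1.37 (percentile 100), and 18 of its 24 measured members were at least 1.5-fold higher and 0 lower. Besides Mmp12 and Spp1, it held Mmp9 (log2 ratio -0.32) and Tgfbi (-0.15) at its lower end. Genes of lysosomes and lipid handling had a median of 0.71 (percentile 100), with 17 of 29 at least 1.5-fold higher and 0 lower, led by Fabp5 and the cathepsin gene Ctsl (1353 against 229 CPM, log2 ratio 2.54). Both lists stayed at percentile 100 without cluster 22, with medians of 0.61 and 0.31.

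Genes of glycolysis and hypoxia had a median of 0.61 (percentile 100), with 11 of 19 members at least 1.5-fold higher, among them Vegfa (log2 ratio 1.79) and Pgam1 (1.36), and Slc2a3 lower (-1.08). Without cluster 22 that median was 0.17 (percentile 95.2). Chemokine genes had a median of 0.59 (percentile 100), and they went both ways: 11 of 21 were at least 1.5-fold higher, such as Cxcl1 (2.47) and Cxcl3 (3.24, with 54.9% of the implanted UMIs in 1 cell), and 4 were lower, such as Cxcl9 and Ccl22 (-1.52). Inflammatory cytokines and mediators had a median of 0.52 (percentile 100), with Acod1 at 0.98 and Il1rn at 0.91, and 3 of 14 members at least 1.5-fold higher. The neutrophil activation and aging list, of which macrophages express many members, had a median of 0.56 (percentile 100), with Csf1 at 61.2 against 18.4 CPM and Cxcr2 at -0.90. It shares Il1b, Tnf, Nfkbia, Il1rn and Ptgs2 with the inflammatory list, and Cxcl2, Ccl3 and Ccl4 with the chemokine list. With no cell filter these 3 lists lay inside the central range, with medians of 0.16 (chemokines), 0.12 (inflammatory) and 0.19 (activation and aging). A lymphocyte effector list with 5 measured genes had a median of 0.67 (percentile 99.7), led by Cd44 (1.29), and oxidative phosphorylation genes had 0.15 (percentile 98.2), with Cox7c at 0.68. The lymphocyte list kept its direction and side under 9 of 17 alternatives and stood at -0.68 with the same weight for every cell, and the oxidative phosphorylation list kept them under 13 of 19 and stood at -0.0718 without cluster 22.

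MHC class II presentation genes were lower in implanted macrophage-like cells, with a median log2 ratio of -0.83 (percentile 0), 11 of 14 members at least 1.5-fold lower and 0 higher. H2-Eb1 had 3166 against 6039 CPM (-0.93), and Cd80, a costimulatory gene, stood at 0.50. Without cluster 22 the median was -0.22 (percentile 0.53). Dendritic cell markers, some of which lay among the leading genes of cluster 10, went both ways over the class: Cd209a had 193 against 290 CPM and Flt3 24.9 against 50.2, while Zbtb46 had 29.4 against 29.7 and Itgax 214 against 43.9. Within cluster 10, Cd209a had 370 and 325 CPM. Proliferation genes had a median of -0.96 (percentile 0), with 14 of 21 at least 1.5-fold lower and 0 higher, and -1.01 (percentile 0) without cluster 22. The share of macrophage-like cells with a UMI of the proliferation marker Mki67 was 12.5% and 13.9% (5.45% and 5.85% thinned), against 1.77% and 1.35% of neutrophil-like cells (0.450% and 0.356% thinned). For Top2a the share was 6.25% and 12.6% (1.98% and 5.85% thinned), against 0.589% and 1.17% of neutrophil-like cells (0% and 0.534% thinned, where 0 of 1334 cells allows up to 0.276% by the exact interval), and Cenpf was detected in 6 and 19 cells.

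Neutrophil granule genes were lower, with a median of -0.57 (percentile 0), Mmp8 at -1.02 and Cd177 at -1.01, but the median turned to 0.10 with 2 times the doublets removed and to 0.265 with 3000 variable genes and 50 components. Of the 16 measured members, 12 are markers of other classes. The list therefore cannot tell macrophage expression from RNA of the neutrophil lineage in the class. Elane was higher (2.13), with 80.9% of its implanted UMIs in 1 cell. The neutrophil transcript S100a8 had 14094 CPM in implanted and 23186 in non-implanted macrophage-like cells, and the precursor transcript Camp 3669 and 6794. Resident macrophage genes had a median of -0.37 (percentile 0.03), with Cd163 at -0.85 and Mrc1 at -0.68, against Ccl8 at 2.24, with 63.2% of the implanted UMIs in 1 cell, and Igf1 at 1.45. That median was -0.0035 (percentile 35.2) without cluster 22, -0.0520 with each library clustered separately, and turned to 0.28 with cells thinned to 1000 UMIs. Alternative activation genes had a median of -0.34 (percentile 0.46) and went both ways, with Arg1 at 4.03 and Ccl24 at 1.64 against Mgl2 at -1.07, and the list kept its direction and side under 12 of 19 alternatives. Ribosomal protein genes, pseudogenes among them, had a median of -0.11 (percentile 1.33), which turned to 0.25 with no cell filter and 0.0376 with no doublets removed.

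**Figure D3:**
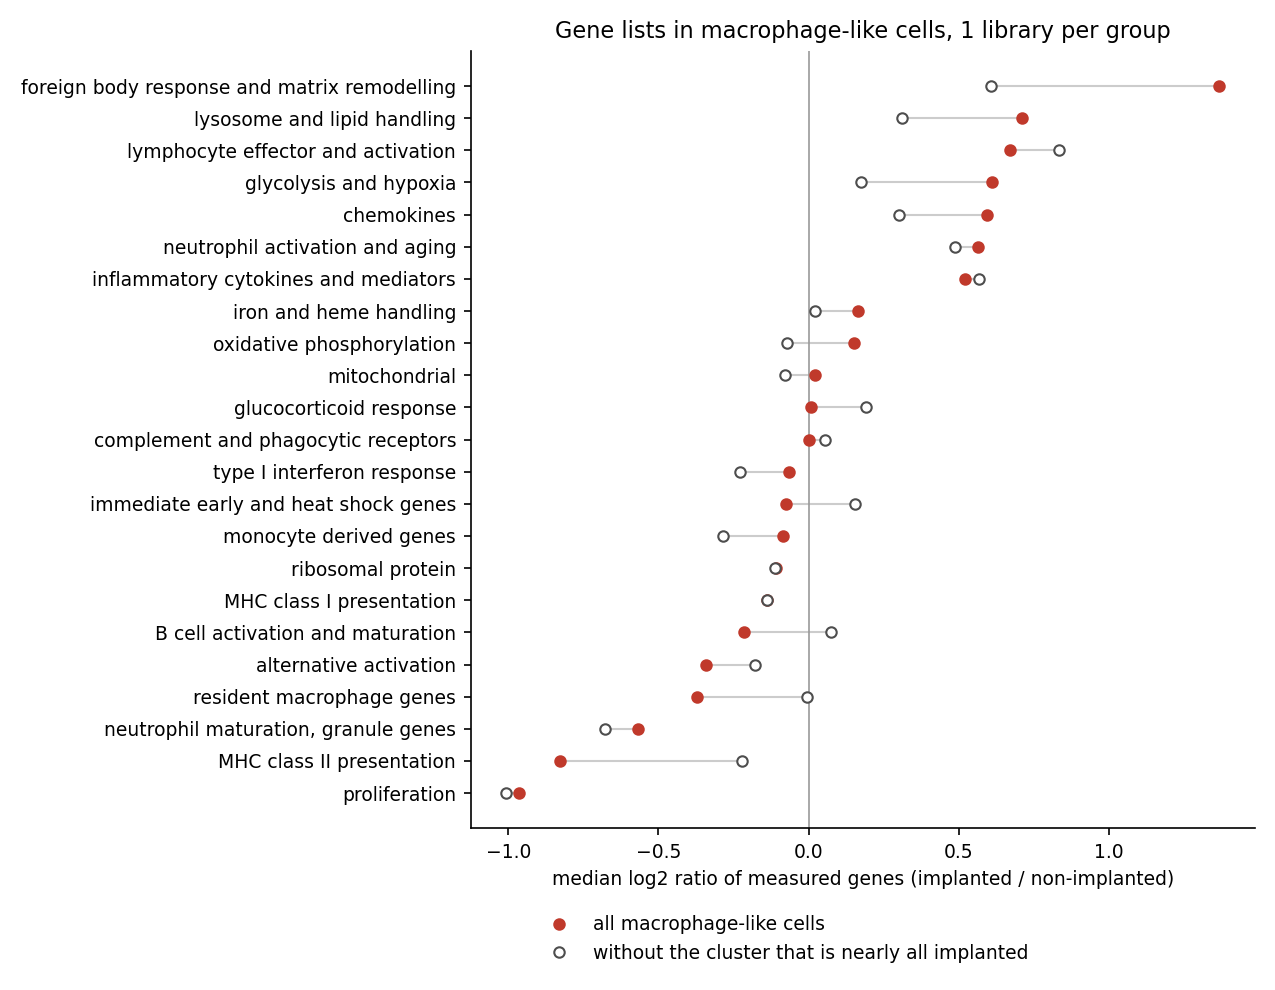
Median log2 ratio (implanted over non-implanted) of the measured genes of each list in all macrophage-like cells (red) and without cluster 22, which was nearly all implanted (open circles). Foreign body and matrix genes lie at 1.37 and 0.61, MHC class II genes at -0.83 and -0.22, and proliferation genes at -0.96 and -1.01.

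The other 9 lists lay inside the central range in all macrophage-like cells together, but some left it without cluster 22. Genes that respond to glucocorticoids, which matter here because the series concerns electrodes with and without dexamethasone, had a median of 0.01 (percentile 60.7). They went both ways, with Sgk1 at 1.87 (333 against 87.8 CPM) and Klf9 at 1.16 against Sult1a1 at -0.94 and Lcn2 at -0.91. Sgk1 had 699 CPM in the implanted cells of cluster 22. In cluster 10 it had 93.6 CPM in the implanted and 76.0 in the non-implanted library, with overlapping intervals. The labels do not say whether the implanted electrode carried the drug, and the median ranged from -0.15 to 0.46 over 19 alternatives. Type I interferon response genes had a median of -0.06 (percentile 31.2), complement and phagocytic receptor genes 0.00 (percentile 56.6) with the integrin gene Itgb2 at 1.05, and MHC class I genes -0.14 (percentile 10.7). Monocyte derived genes had -0.09 (percentile 24.1) with Fn1 at 3.50 and Ccr2 at -1.07, and iron and heme genes 0.17 (percentile 92.7) with the ferritin gene Fth1 at 1.31. In the implanted cells of cluster 22, Itgb2 had 744 and Fn1 1975 CPM. In cluster 10, Itgb2 had 201 CPM in the implanted and 192 in the non-implanted library, and Fn1 57.2 and 27.7. Immediate early and heat shock genes had -0.08 (percentile 18.4) with Hspa1b at -1.30 and Hspa1a at -1.21, B cell genes -0.21 (percentile 6.68), and mitochondrial genes 0.02 (percentile 67.0). Without cluster 22, medians lay below the central range for monocyte derived (-0.28, percentile 0), interferon response (-0.23, percentile 0.28) and MHC class I genes (-0.14, percentile 2.025). They lay above it for glucocorticoid response (0.19, percentile 97.53) and immediate early and heat shock genes (0.15, percentile 98.4). The complement, iron and heme, B cell and mitochondrial lists stayed inside it.

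In monocyte-like cells the differences were smaller. Inflammatory cytokines and mediators were higher in the implanted library, with a median log2 ratio of 0.45 (percentile 100), led by Nfkbia (798 against 455 CPM, 0.80) and Il1rn (0.79). Of the 15 measured members, 4 were at least 1.5-fold higher and 0 lower. The chemokine genes Cxcl10 (124 against 40.6 CPM, ratio 3.06, 2.35 to 4.04) and Cxcl2 (296 against 126 CPM, ratio 2.34, 2.01 to 2.75) were higher, and Cxcl10 was detected in 26 and 7 cells. MHC class II genes had a median of 0.23 (percentile 100), opposite in sign to macrophage-like cells, with Ciita at 0.49, and interferon response genes 0.18 (percentile 100) with Oasl2 at 0.86. The foreign body and matrix list had 0.14 (percentile 99.5), with Spp1 at 0.99, and Ctsk at 3.61 with 93.3% of its UMIs in 1 cell. That list lay inside the central range with cells thinned to 1000 UMIs and with at least 100 UMIs per gene (0.0736), while the inflammatory, MHC class II and interferon lists stayed outside it under all 9 alternatives.

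Of the other named genes of monocyte-like cells, the lysozyme gene Lyz1 had a ratio of 4.03 (3.05 to 5.41), Hist1h1b 2.97 (1.97 to 4.61) and the pseudogene Tpt1-ps3 2.38 (1.86 to 3.06). In the implanted and non-implanted library, 1 cell held 27.4% and 55% of the Lyz1 UMIs, and 1 cell 33.0% and 33.3% of the Hist1h1b UMIs. The copies Lyz1 and Tpt1-ps3 can share reads with Lyz2 and Tpt1, and their values are uncertain for that reason. The lowest log2 ratios were those of Acvr2a (-0.75), Mir703 (-0.73), Tmcc3 (-0.71), Psmb3 (-0.70) and P4ha1 (-0.68).

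Neutrophil-like cells were spread differently over their clusters, and the differences in their inflammatory genes were smaller with the clusters weighted alike. Cluster 7, led by Acod1, Cxcl2 and Ccrl2, held 15.8% of the implanted and 7.22% of the non-implanted neutrophil-like cells, and cluster 1 held 31.3% and 38.5%. The genes leading cluster 7 are members of the inflammatory, chemokine and activation lists. The same cluster weights therefore shrink the differences of these lists in part by construction. Inflammatory cytokines and mediators had a median log2 ratio of 0.30 (percentile 100), with Cd14 at 1.05 and Il1a at 0.72, but 0.0416 (percentile 79.1) when each cluster was given the same weight in both libraries. The activation and aging list, with Icam1 at 1.06, Ccrl2 at 0.66, Cxcr4 at -0.15 and Siglecf at -0.63, had 0.16 (percentile 100) and 0.00578 (percentile 42.8) with the same cluster weights. Chemokine genes had 0.23 (percentile 99.8) and 0.13 (percentile 98.1). With the same weights, the granule (0.13), mitochondrial (0.17), foreign body (0.12) and B cell (0.18) lists also stayed above the central range. The resident macrophage (0.19) and glycolysis (-0.0342) lists moved inside it. Of the 7 measured members of the resident macrophage list, 6 are markers of other classes.

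Of the named genes of neutrophil-like cells, Nfkbie, an inhibitor of NF-kappa B, had 53.1 against 27.5 CPM (ratio 1.93, 1.56 to 2.40) and the subunit gene Relb 82.5 against 44.0 (ratio 1.87, 1.58 to 2.23). Their log2 ratios were 0.84 and 0.84, and 0.37 and 0.41 with the same cluster weights. Dock10, Rbpj and Dusp16 had log2 ratios of 0.99, 0.76 and 0.74, and 0.53, 0.54 and 0.31 with the same weights. The lowest were Psenen (-0.71), Prex2 (-0.62), Slc15a2 (-0.54), Fgfr2 (-0.53) and Myl6 (-0.51). Immediate early and heat shock genes had a median of -0.10 (percentile 0), and -0.0231 (percentile 5.46) with the same weights.

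Granulocyte precursor-like cells differed the other way in the inflammatory, activation and chemokine lists, which share members. Cluster 2, led by Ly6g and Ltf, held 38.2% of the implanted and 52.3% of the non-implanted precursor-like cells, cluster 6 held 23.1% and 11.2%, and cluster 13, led by Elane, Prtn3, Mpo and Ctsg, 8.07% and 6.24%. The chemokine genes of precursor-like cells had a median of -0.47 (percentile 0), inflammatory cytokines and mediators -0.20 (percentile 0), with Il1b at -0.68 and Acod1 at -0.62 against Cd14 at 0.75, and the activation and aging list -0.18 (percentile 0). Proliferation genes had a median of 0.19 (percentile 100), with Cdk1 at 0.39. With the same cluster weights in both libraries these medians were -0.42, -0.15, -0.15 and 0.0962, all still outside the central range. Inside it lay the chemokine list with at least 1 UMI per gene (-0.0209), the activation and aging list with the same weight for every cell (-0.0429), and the proliferation list with cells thinned to 1000 UMIs (0.0733). Among the named genes, the granule protease gene Ctsg had 116 against 45.0 CPM (ratio 2.56, 2.30 to 2.86), the myeloperoxidase gene Mpo 321 against 159 (ratio 2.01, 1.89 to 2.14), and Hist1h2ap, Cnnm2 and Olfm4 had log2 ratios of 1.42, 0.89 and 0.78. The Ctsg UMIs lay in 71 implanted and 67 non-implanted cells, and 1 cell of each library held 16.6% and 19.2% of them. With the same cluster weights the log2 ratio was 0.84 for Ctsg (1.27 without), 0.52 for Mpo (0.99) and 0.24 for Cnnm2. Prex2 (-0.67), Myl6 (-0.62), Camk1d (-0.59), Ppia (-0.53) and Egr1 (-0.50) had the lowest, with Ppia at -0.62 and Egr1 at -0.19 with the same cluster weights. The median of the inflammatory list turned to 0.0470 (percentile 46.2) when cells were thinned to 1000 UMIs.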

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

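Each group had 1 library, so leaving out a replicate was not possible, and every value here describes these 2 libraries. No paired analysis was possible because each group had 1 library and the labels do not link the libraries by animal. In macrophage-like cells, 4 of the 14 lists outside the central range kept direction and side under all 19 alternatives: foreign body and matrix genes (medians 0.61 to 1.53), lysosome and lipid genes (0.31 to 1.06), MHC class II genes (-1.67 to -0.22) and proliferation genes (-1.21 to -0.56). The difference in share stayed at -6.36 to -5.12 points for the neutrophil lineage, 2.13 to 2.76 for monocyte-like and 0.857 to 1.38 for erythroid-like cells, the last without a value among white blood cells alone, which leave that class out. Counts of genes past a fixed size were planned, moved by over 1.5 times in 13 of 38 comparisons in macrophage-like, 12 of 18 in precursor-like, 9 of 18 in monocyte-like and 5 of 18 in neutrophil-like cells, and are not reported. Of the shares, the medians of named genes and the 14 lists, the values that lay outside the counting interval of the reported value or inside the central range follow, with all that turned, as median log2 ratios in macrophage-like cells unless a share is named, and the cause was not tested. With no cell filter: 12 highest genes 4.37, 12 lowest -1.42, inflammatory list 0.12, chemokines 0.16, neutrophil activation 0.19, lymphocyte effector 0.0266, ribosomal 0.25 (turned). With no doublets removed: 12 lowest -1.79, lymphocyte effector 0.0622, ribosomal 0.0376 (turned). With 2 times the doublets removed: alternative activation -0.0818, oxidative phosphorylation 0.0868, granule genes 0.10 (turned). At Leiden resolution 0.5: share of neutrophil-like cells -1.38 points (48.0% and 49.3%), of precursor-like cells -4.61 (27.9% and 32.5%), alternative activation -0.0531. At Leiden resolution 2: 12 lowest -1.85, lymphocyte effector 0.40, ribosomal -0.00254. With 3000 genes and 50 components: 12 highest 4.26, alternative activation -0.24, resident genes -0.20, oxidative phosphorylation 0.0351, granule genes 0.265 (turned), lymphocyte effector -0.11 (turned). With each library clustered separately: share of neutrophil-like cells -10.1 points (44.2% and 54.3%), of precursor-like cells 4.475 (32.0% and 27.5%, turned), of macrophage-like cells 0.0212 (7.14% and 7.12%), alternative activation -0.20, resident genes -0.0520, oxidative phosphorylation 0.16, lymphocyte effector 0.0157. With cells thinned to 1000 UMIs before clustering: share of neutrophil-like cells -2.925 points (51.4% and 54.3%), of precursor-like cells -2.83 (25.7% and 28.5%). In precursor-like cells: 5 highest genes 0.91 and 5 lowest -0.66 under edgeR TMM and likewise 0.91 and -0.66 under median-of-ratios scaling, 5 lowest -0.51 with a pseudocount of 20, and, thinned to 1000 UMIs, inflammatory list 0.0470 and MHC class II 0.39 (both turned). Macrophage-like cells thinned to 1000 UMIs: 12 lowest -1.88, resident genes 0.28 (turned), oxidative phosphorylation 0.0539, ribosomal -0.10. With the same weight for every cell: 12 highest 3.11, 12 lowest -1.31, resident genes -0.19, oxidative phosphorylation 0.0848, lymphocyte effector -0.68 (turned). With a pseudocount of 1: 12 highest 5.05. With a pseudocount of 20: 12 highest 2.79, 12 lowest -1.23, and the 5 highest in monocyte-like cells 1.11 and in neutrophil-like cells 0.65. Monocyte-like cells thinned to 1000 UMIs: 5 highest 1.01. With at least 1 UMI: alternative activation -0.21, lymphocyte effector -0.1125 (turned). The next were added after the data were seen. Without cluster 22: 12 highest 0.69, resident genes -0.0035, glycolysis and hypoxia 0.17, oxidative phosphorylation -0.0718 (turned), Mamdc2 -0.12 and Arg1 -0.0895 (both turned). Without the shallow cluster 15: alternative activation -0.0531. Without each gene's top cell: alternative activation 0.00, lymphocyte effector 0.33. With each cluster weighted the same in both libraries: 5 highest genes 0.84 in precursor-like and 0.41 in neutrophil-like cells, immediate early genes of precursor-like cells 0.0422 (turned). Here the alternative's construction takes out the different make-up of the classes. Over all alternatives, 18 values of the other 9 lists of macrophage-like cells moved out of the central range. Lists of the other classes, some of them named in the report, moved into it 25 times and out of it 5 times in precursor-like, 14 and 7 times in monocyte-like and 9 and 9 times in neutrophil-like cells. In monocyte-like cells those that moved into it were the chemokine, foreign body, lymphocyte effector and ribosomal lists. Of the log2 ratios of single named macrophage-like genes, 82 lay outside their counting interval, 2 turned and 372 lay inside it.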

Other observations

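B cell-like cells, 40 in the implanted and 32 in the non-implanted library, held Ighm, the gene of the immunoglobulin M heavy chain, at 22534 CPM (3980 UMIs) and 3182 CPM (555 UMIs). Ighm was detected in 39 and 32 of these cells. Neutrophil-lineage transcripts stood the other way in the class, with S100a8 at 459 and 17466 CPM, Camp at 164 and 5539 and Ngp at 311 and 4587. The class had fewer than 100 cells in each library and was not compared gene by gene. In macrophage-like cells Ighm had 89.5 and 185 CPM, the osteoclast enzyme gene Acp5 134 and 26.9, and Ptgds 27.8 and 74.3. The beta-globin gene Hbb-bs had at least 1 UMI in 21.8% of all implanted and 11.4% of all non-implanted cells.

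For foreign body and matrix genes in implanted macrophage-like cells all the tests were chosen after the result was seen, and where a first version had been run both are given. Without each gene's 3 top cells in each library, the list's median was still 1.15 (percentile 100). This removal takes a larger part from the library with fewer positive cells (Mmp12 had 27 implanted and 2 non-implanted), which can raise the ratio. It therefore cannot exclude that a few cells carried part of the list. It replaced the median share of UMIs in the 3 top cells (26.1%, lowest member 11.4 and highest 83.3). That first version had decided nothing and was itself moved from the 12 highest genes to the 18 higher list members. Osteoclast RNA, scaled as if all the Acp5 excess were of that origin, gave a median of 0.304% (0.00656 to 2.37) of the excess. For Ctsk it gave 110% (106 to 115) and could account for that gene's excess. The Ctsk interval covers only the osteoclast-like Ctsk count, not the Acp5 scaling or the macrophage-like excess. Here and for free RNA, the range beside a median over list members comes from resampling the members and is not counting error. Free RNA is unlikely for 12 higher members, Spp1, Mmp12 and Gpnmb among them, which had under 10% of their macrophage-like level in implanted neutrophil-like cells. In the same test Timp2 (101%), Vegfa (103%), Cd44 (107%), Cd9 (140%) and Thbs1 (579%) lay past the level set as the mark of free RNA, and Lgals3 (19.7%) lay between the bounds. That test cannot tell free RNA from transcripts made by the neutrophil-like cells themselves. For these genes a later version used the UMIs per implanted erythroid-like cell. They gave a median of 8.37% (3.25 to 16.8) of the excess per macrophage-like cell, and at most 29.6% for Cd44. By that version free RNA is a small part of the excess, if it is alike in all droplets. A first version over all members (2.05%, 0.881 to 54.5) had left the question open. With 1 library per group, an effect of the electrode cannot be told apart from any other difference between the libraries.

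For lower proliferation genes in implanted macrophage-like cells the tests on the list's top cells and on precursor RNA were written before the result was seen, and the value without each gene's top cells was added after. The 3 top non-implanted cells held 18.5% (17.3 to 19.7) of the list's UMIs, so that by this share a few cells did not carry the list. For single lower members, each gene's own 3 top cells held a median of 35.7% (lowest member 20.6 and highest 57.8). Without each gene's 3 top cells in each library the median was -0.99 (percentile 0). That removal takes a larger part from the library with fewer positive cells (Cenpf had 6 implanted and 19 non-implanted), which can lower the ratio, so it decides nothing by itself. Precursor RNA scaled by Camp gave a median of 21% of the deficit (17.1 to 27.3 when the list members were resampled), and its part cannot be told apart. That explanation had been ruled out on the first value alone, and the spread that left it open was added after that value had been seen.

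Hbb-bs had 1082 CPM in implanted and 94.1 in non-implanted macrophage-like cells, and of the 2 tests the one on free RNA was chosen after the result was seen. Of the implanted UMIs in macrophage-like and monocyte-like cells, 93.4% (92.6 to 94.2) lay in 3 cells, so that a few cells, perhaps joined to an erythroid cell, could carry the difference. Free RNA spread over all cells was tested by the UMIs per cell over those of neutrophil-like cells, a ratio of 36 (31.7 to 41.1), which rests on the same few cells. Without the 3 top cells of each class Hbb-bs had 67.8 and 23.8 CPM in macrophage-like and 37.2 and 33.0 CPM in monocyte-like cells.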
